A study of Mus musculus with 8 samples.

How the data were processed

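Total RNA from mouse liver was sequenced as 8 libraries, 4 from mice that had received a control short hairpin RNA (shNC) and 4 from mice that had received a hairpin against Tbl1xr1 (shTbl1xr1), both carried to hepatocytes by an adeno-associated virus. Per the labels' protocols, the virus was given 4 weeks before partial hepatectomy, the surgical removal of most of the liver, and liver was taken on day 2 after surgery. RNA was extracted with TRIzol and made into libraries with an MGIEasy RNA kit, per the labels' protocols. The labels number the replicates of each group but do not say that each is a separate animal, so p-values measure only the spread between these libraries, which may in part be technical. No sequencing batch or date is given in the sources used here.

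For each library the authors deposited 1 table with 55401 genes. Per the file headers, each table holds an expected count, which is the authors' estimate of fragments per gene and need not be whole, together with the gene's length and effective length. The deposited TPM and FPKM columns are those expected counts scaled by length and by library total, per the file headers, and were read to check the files but not tested. The submitters' processing notes name STAR, RSEM, DESeq2 1.30.1 and the build mm10, without options. The strand setting and the annotation release are not given in the sources used here. RSEM shares fragments that align to several genes among them by likelihood, so values of near-identical genes, such as members of the Gst, Cyp2, Orm and Mup families, are uncertain. Symbols and coordinates came from GENCODE mouse release 21 on GRCm38, the assembly that mm10 denotes. Of the 55401 gene identifiers, 55141 had a symbol there without regard to the version suffix and 54349 matched with it.

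Expected counts were rounded to whole numbers. Library totals were 25811763 to 27537235 counts in shNC and 10895508, 10728583, 26976205 and 36720879 counts in shTbl1xr1 1 to 4, so low levels, given as library-scaled CPM, carry more counting error in shTbl1xr1 1 and 2. Genes with enough counts were kept by filterByExpr, which left 13908, and libraries were scaled by TMM in edgeR 4.0.16 under R 4.3.3. Groups were compared by edgeR's quasi-likelihood F test with robust dispersions and no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Printed CPM values are TMM-normalised, and log2 levels per library used a prior count of 2. The level of Tbl1xr1 was also compared by a two-sided exact permutation test over the 70 arrangements of the 8 libraries, on log2 of CPM plus 1.

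The samples, the test, the threshold, 28 gene lists, the rule for named genes and 20 processing alternatives were fixed before the data were examined. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1, with a preset correlation between genes of 0.01, and adjusted over the 27 lists that qualified. Each list was also tested with the correlation estimated from the data, which is stricter, and by fry, which asks whether its members move one way without reference to other genes. The lists were corepressor complex, DNA replication, mitosis, p53 targets, fatty acid oxidation, lipogenesis, cholesterol synthesis, bile acid synthesis and transport, pericentral and Wnt, periportal, hepatocyte identity, drug metabolism, oxidative stress, stress response, acute phase, interferon response, immediate early, YAP and TGF beta targets, circadian clock, sex-biased liver genes, fetal liver genes, macrophages, neutrophils, lymphocytes, stellate cells, endothelial cells, cholangiocytes and red blood cells. An exact permutation test of each list's mean log2 level over the 35 ways to part the 8 libraries into 4 and 4 was added after the data were seen. Its smallest possible p is 0.0286, so an adjusted p under 0.05 over the 27 lists would need most lists at that value. Its adjusted p therefore says little about any single list.

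The rule named the corepressor subunits, of which 1 is not reported here, then up to 12 genes with the largest rise and 12 with the largest fall past the threshold. Those had to have a mean CPM of at least 5, groups that did not overlap, and a symbol that is not a predicted gene or pseudogene name. It also named, per list, up to 2 members per direction past the threshold or otherwise the member with the smallest p, and Mki67, Pcna, Ccnd1, Cdkn1a, Alb, Glul, Axin2, Cpt1a and Fgf21 in any case. Pls1, and members past the threshold over their list alone that the rule had not taken, were named after their values were seen.

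The tests were checked on simulated counts drawn from the real means and library sizes with 200 changed genes. Genes were drawn independently, without a shift shared by several libraries, so the rates below hold for that simpler setting. For shTbl1xr1 against shNC, edgeR recovered 23.5% of the genes changed 2-fold and 75.5% of those changed 4-fold, with 1.02% false calls among 98 called of 13767 tested. DESeq2 1.42.0 recovered 48.0% and 88.0% with 20.5% false calls. The 20 fixed alternatives were other normalizations, filters and tools (DESeq2, limma-voom), counts not rounded, no robust option, the replicate number as a block, removal of mitochondrial and the 10 most abundant genes, 1 surrogate variable (sva 3.50.0), and each library left out. A fold threshold and other list tests were fixed beside them. After the data were seen, the 2 shallowest libraries, shTbl1xr1 1 and 2, stood apart, and fits without them, without the other pair, after thinning to equal total counts, with library weights and after removal of each library's trend over transcript length were added, as were list tests under upper quartile and library size scaling. Nothing was left out of the main comparison.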

Results

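Liver transcriptomes were measured on day 2 of regeneration after partial hepatectomy in mice whose hepatocytes had received shNC or shTbl1xr1 4 weeks earlier, with 4 libraries per group. The comparison asks which transcripts depend on Tbl1xr1, a subunit of the NCoR corepressor complex, in the regenerating liver. Libraries shNC 1 to 4 held 25811763, 27537235, 25890652 and 25833345 expected counts, and shTbl1xr1 1 to 4 held 10895508, 10728583, 26976205 and 36720879. Mitochondrially encoded genes took 11.3% and 14.8% of counts in shTbl1xr1 1 and 2, called the shallow libraries here, and 4.52% to 7.34% in the other 6. The first principal component, with 59.3% of the variance, placed the shallow libraries at 86.0 and 86.4 and the other 6 between -39.7 and -9.29. Both shallow libraries are shTbl1xr1, and no shNC library had so few counts.

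**Figure D1:**
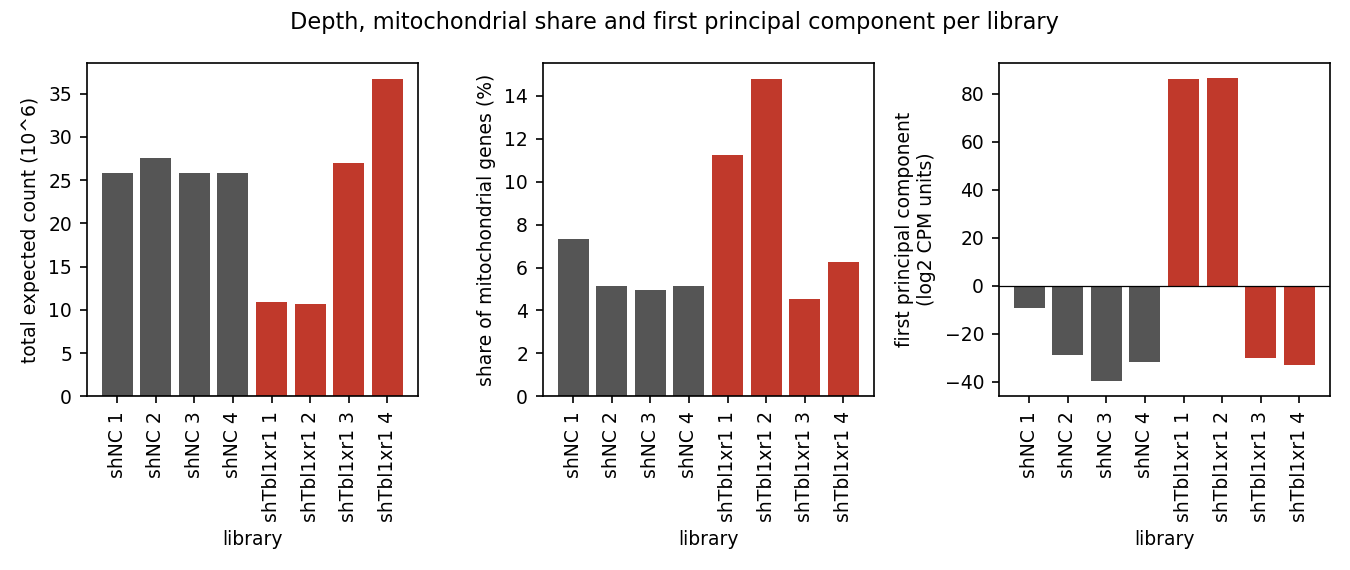
Bars give, for each of the 8 libraries, the total expected count, the share of counts in mitochondrially encoded genes in percent, and the score on the first principal component of log2 CPM, with shNC in grey and shTbl1xr1 in red. Libraries shTbl1xr1 1 and 2 have totals of 10895508 and 10728583, the highest mitochondrial shares and scores of 86.0 and 86.4.

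The targeted gene was lower in all 4 shTbl1xr1 libraries than in any shNC library. Tbl1xr1 (ENSMUSG00000027630.13; chromosome 3, 22076652 to 22216594, plus strand, mm10) had 32.8 ± 3.84 CPM in shNC and 7.40 ± 6.57 CPM in shTbl1xr1 (SD, n = 4 each), a mean of 22.5% of shNC. The knockdown was uneven, with 2.38 and 2.07 CPM in the shallow libraries and 9.24 and 15.9 CPM in shTbl1xr1 3 and 4, or 6.78% and 38.3% of the shNC mean. The groups did not overlap, and the two-sided exact permutation p of 0.0286 is the smallest that 4 against 4 can give. The log2 fold change of -2.07 (SE 0.54) did not pass the edgeR threshold over all genes (adjusted p = 0.290). It passed with 1 surrogate variable (log2 fold change -1.67, adjusted p = 0.00739) and with DESeq2 (-2.13, adjusted p = 0.00852), and ranged from -3.88 with the shallow shTbl1xr1 pair only to -1.38 with the deeper libraries only.

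None of the corepressor subunits passed the threshold over all genes. Tbl1x, the closest paralog of Tbl1xr1, had a log2 fold change of 0.44 (SE 0.15) and the deacetylase Hdac3 one of 0.44 (SE 0.15), both with adjusted p of 0.38 and with all 4 shTbl1xr1 libraries above every shNC library. Adjusted over the list alone, 2 of the 6 members (Tbl1x and Hdac3) were higher and 1 (Tbl1xr1) was lower. Ncor1 and Gps2 had log2 fold changes of -0.33 and 0.17, and the direction of Gps2 turned when libraries were scaled by size alone (-0.16). As a list the complex, Tbl1xr1 included, did not pass by camera (adjusted p = 0.984), with a mean of -0.20 and a median of 0.15, but passed by fry for change in either direction (adjusted p = 0.0234). Since the hairpin's target is a member, that pass could come from the target itself and says little about the other subunits.

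Of 13908 genes tested, 6 rose and 1 fell in shTbl1xr1, and 3 and 1 when libraries were scaled by size alone. The largest rise was in Gstm3, a glutathione S-transferase, from 97.4 ± 16.3 to 1151 ± 549 CPM (SD, n = 4 each), a log2 fold change of 3.56 (SE 0.35, adjusted p = 0.0142). Cyp2a5, a monooxygenase of xenobiotic metabolism, rose from 80.4 ± 12.6 to 528 ± 111 CPM (log2 fold change 2.72, SE 0.22, adjusted p = 0.00476), and its relative Cyp2c55 rose from 15.7 ± 3.78 to 47.1 ± 6.71 CPM (1.58, SE 0.20, adjusted p = 0.0459). The acute phase protein gene Orm2 rose from 125 ± 35.3 to 611 ± 187 CPM (2.29, SE 0.30, adjusted p = 0.0475). Cd276, an immune checkpoint molecule of the B7 family, rose from 8.34 ± 1.13 to 21.1 ± 2.08 CPM (1.35, SE 0.16, adjusted p = 0.0416). Pls1, which encodes an actin-bundling plastin and was named after its values were seen, rose from 0.994 ± 0.212 to 8.16 ± 4.10 CPM (3.06, SE 0.39, adjusted p = 0.0459). Cyp2b9, a female-biased liver gene, fell from 14.0 ± 8.56 to 0.159 ± 0.157 CPM (adjusted p = 0.0427), with 507, 325, 117 and 687 counts in shNC 1 to 4 and 3, 1, 0 and 5 counts in shTbl1xr1 1 to 4. Gstm3, Cyp2a5, Cyp2c55, Orm2 and Cyp2b9 have close paralogs, so their counts are uncertain.

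Gstm3 lies on chromosome 3 (107963696 to 107969283, minus strand), Cyp2a5 and Cyp2b9 on chromosome 7 (26835305 to 26843548 and 26173411 to 26210661, both plus strand), and Cyp2c55 on chromosome 19 (39007019 to 39042693, plus strand). Orm2 lies on chromosome 4 (63362449 to 63365878, plus strand), and Cd276 and Pls1 on chromosome 9 (58524298 to 58555437 and 95752642 to 95845311, both minus strand). These positions are whole annotated genes in mm10. For each of the 7 genes, every shTbl1xr1 library lay on one side of every shNC library. The 4 genes Gstm3, Cyp2a5, Cd276 and Pls1 also passed in the deeper libraries only, 4 shNC against 2 shTbl1xr1, where Cyp2c55, Orm2 and Cyp2b9 did not (adjusted p = 0.116, 0.116 and 0.137). When libraries were scaled by size alone, Gstm3, Cyp2c55, Cd276 and Pls1 did not pass (0.0595, 0.222, 0.490 and 0.244) and the predicted gene Gm3839, named after its values were seen, did (0.0437). Orm2 did not pass with DESeq2's size factors in edgeR (0.0516), nor Pls1 with upper quartile scaling (0.0557) or limma-voom (0.0546), nor Cyp2b9 with limma-voom (0.163). Without shNC 1, shNC 2 or shNC 4, edgeR called 0 genes, where 844, 631 and 644 genes were higher and 372, 297 and 292 lower at an unadjusted p under 0.05. Without shNC 3, Cyp2a5 and Cyp2b9 passed, and 2 (Gstm3 and Cyp2a5), 3 (with Pls1) and 3 (with Orm2) genes passed without shTbl1xr1 1, 2 and 3. Without shTbl1xr1 4, 28 genes were higher and 6 lower, all 7 among them.

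**Figure D2:**
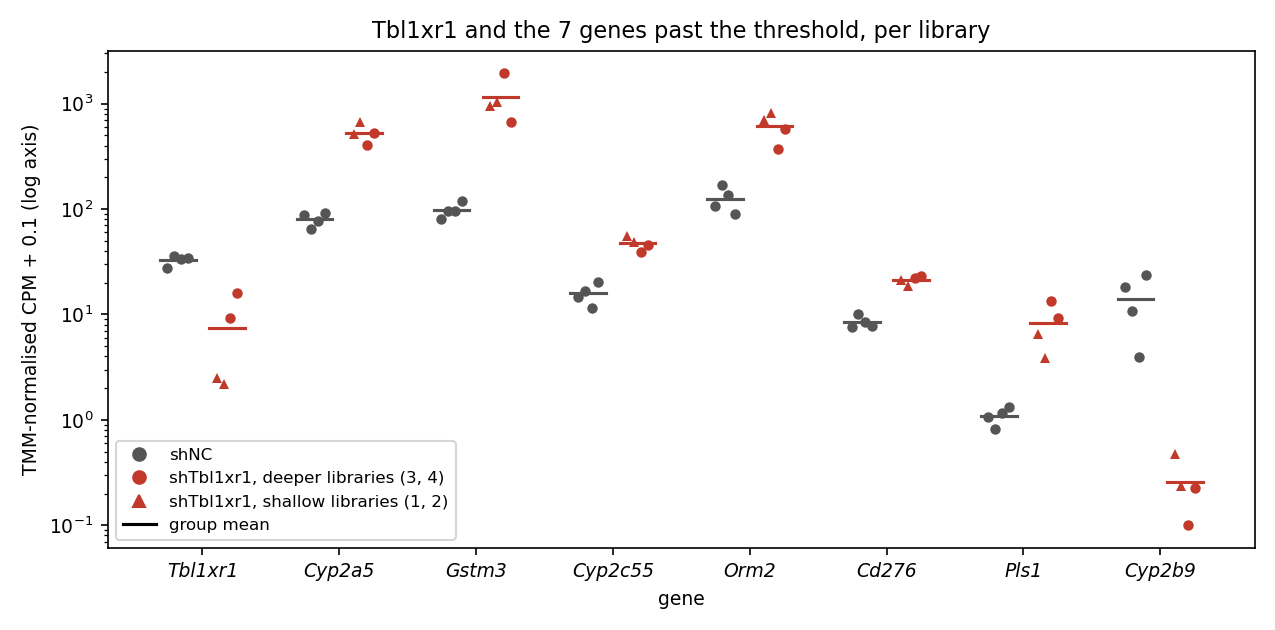
Points give TMM-normalised CPM plus 0.1 on a log axis for Tbl1xr1 and the 7 genes past the threshold in each library, with grey circles for shNC, red triangles for shTbl1xr1 1 and 2, red circles for shTbl1xr1 3 and 4, and lines at group means of 4 libraries. For each gene the 2 groups do not overlap, and Tbl1xr1 is lowest in shTbl1xr1 1 and 2, at 2.38 and 2.07 CPM before the constant was added.

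Over all tested genes, 1099 were higher and 516 lower at an unadjusted p under 0.05, against 776 and 753 with upper quartile scaling and 252 and 887 when libraries were scaled by size alone. The groups did not overlap for 1008 genes, or 7.25%, where the average over all splits of the libraries into 4 and 4 is 2.86%. Genes move together, so single splits can lie far from that average, and they were not counted. DESeq2 called 237 genes higher and 39 lower, and a fit with 1 surrogate variable called 38 and 4.

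Enzymes of drug metabolism were higher as a list in shTbl1xr1 (camera adjusted p = 3.5e-11, and adjusted p = 0.165 with an estimated correlation). Of 18 tested members, 15 had positive log2 fold changes, 2 rose over all genes (Cyp2a5 and Cyp2c55), and 7 were higher and 0 lower when adjusted over the list alone. Among those 7, the monooxygenase Cyp2c29 had 487 ± 49.6 CPM in shNC and 1427 ± 742 CPM in shTbl1xr1 (log2 fold change 1.55, SE 0.38), and Sult1a1, a sulfotransferase, 251 ± 39.4 and 410 ± 32.9 CPM (0.71, SE 0.18). Por, the reductase that passes electrons to such monooxygenases, Ces2a and Fmo5 had log2 fold changes of 0.61, 0.85 and 0.68. The mean log2 level of the list was 0.65 higher than in shNC, with all 4 shTbl1xr1 libraries above the shNC range (exact permutation p = 0.0286, adjusted p = 0.257 over 27 lists). The margin was narrow, with 0.214 in shTbl1xr1 3 and 0.210 in shNC 4 relative to the shNC mean.

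NRF2 target genes of the oxidative stress list were also higher (camera adjusted p = 1.8e-09, and adjusted p = 0.165 with an estimated correlation). Gstm3 rose over all genes, and adjusted over the list alone 6 of 15 members were higher and 0 lower. The glutathione S-transferases Gsta2, Gstm1 and Gsta1 had log2 fold changes of 1.81, 1.85 and 1.72, and the pentose phosphate enzymes Pgd and Tkt 0.77 and 0.54. Gsta2 passed over all genes without a filter on low counts (adjusted p = 0.0203). The list's mean level was 0.72 higher, above the shNC range in all 4 shTbl1xr1 libraries (exact permutation p = 0.0286, adjusted p = 0.257). By fry, drug metabolism and oxidative stress both passed (adjusted p = 0.0447 and 0.0398), and 5 of 27 lists passed for change in either direction. These were the same 2 (both 0.000375), lipogenesis (0.0203), the corepressor complex, which holds the targeted Tbl1xr1, and the sex-biased genes. Drug metabolism and oxidative stress were called by camera under each of the 4 scalings tried and with each of the 8 libraries left out.

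Genes of fatty acid and triglyceride synthesis were higher as the lipogenesis list (camera adjusted p = 7.2e-05, and adjusted p = 0.380 with an estimated correlation). Of 19 tested members 18 had positive log2 fold changes, and 0 passed over all genes. Adjusted over the list alone 3 were higher and 0 lower. These were Scd1, the stearoyl-CoA desaturase, at 616 ± 200 CPM in shNC and 1934 ± 645 CPM in shTbl1xr1 (log2 fold change 1.65, SE 0.33), Thrsp at 16.5 ± 6.21 and 75.8 ± 43.5 CPM (2.20, SE 0.49), and Acacb, an acetyl-CoA carboxylase, at 16.1 ± 4.11 and 34.9 ± 18.1 CPM (1.12, SE 0.33). Scd1 passed over all genes with 1 surrogate variable (adjusted p = 0.0174). The list's mean level was 0.49 higher, above the shNC range in all 4 shTbl1xr1 libraries (exact permutation p = 0.0286, adjusted p = 0.257), and its camera call was lost without shTbl1xr1 4 (adjusted p = 0.0551). Relative to the shNC mean it was 0.43, 0.27, 0.31 and 0.97 in shTbl1xr1 1 to 4. The highest level was thus in shTbl1xr1 4, the library with the weakest knockdown.

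Fatty acid oxidation and mitosis were lower as lists. For fatty acid oxidation (camera adjusted p = 0.0112, and adjusted p = 0.803 with an estimated correlation), 23 of 33 members had negative log2 fold changes and 0 passed over all genes. Acadm, a mitochondrial acyl-CoA dehydrogenase, was the 1 member lower when adjusted over the list alone, at 334 ± 17.0 CPM in shNC and 204 ± 8.43 CPM in shTbl1xr1 (log2 fold change -0.71, SE 0.15, adjusted p = 0.196 over all genes), while Cpt1a and Fgf21 had -0.28 (SE 0.20) and 0.78 (SE 1.303). Acadm passed over all genes with DESeq2 (adjusted p = 1.9e-08), 1 surrogate variable (0.0404), the length trend removed (0.0420) and the shallow shTbl1xr1 pair only (0.00228). With 1 library left out its adjusted p was at least 0.0912. The list's mean level lay within the shNC range in all 4 shTbl1xr1 libraries, and its call was lost without shNC 3, shNC 4, shTbl1xr1 3 or shTbl1xr1 4 (adjusted p = 0.13, 0.11, 0.099 and 0.17).

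For mitosis (camera adjusted p = 0.00137, and adjusted p = 0.803 with an estimated correlation), 28 of 33 members had negative log2 fold changes, and 0 passed over all genes or over the list alone. Mki67 had 76.2 ± 24.2 CPM in shNC and 55.5 ± 1.21 CPM in shTbl1xr1 (log2 fold change -0.46, SE 0.22) and Prc1, which bundles spindle microtubules, -0.68 (SE 0.23). The list's mean level lay below the shNC range in 1 of 4 shTbl1xr1 libraries, 10 of 35 splits gave a difference as large (exact permutation p = 0.286), and the call was lost without shNC 2 or shTbl1xr1 4 (adjusted p = 0.078 and 0.25). DNA replication genes did not pass (camera adjusted p = 0.0855), with 24 of 35 log2 fold changes negative, Ung at -0.57 and Pcna at 0.12. The list was lower and passed without shNC 1, shNC 2, shTbl1xr1 1 or shTbl1xr1 4 (adjusted p = 0.0315, 0.0161, 0.0446 and 0.0015) and with the length trend removed (0.0207), all at the preset correlation. With an estimated one, over all libraries, its adjusted p was 0.803. Ccnd1, which encodes cyclin D1, had 192 ± 34.2 CPM in shNC and 79.9 ± 25.6 CPM in shTbl1xr1 (log2 fold change -1.26, SE 0.26, adjusted p = 0.18). It passed with DESeq2 (adjusted p = 0.000801), limma-voom with sample weights (0.0349) and the shallow shTbl1xr1 pair only (0.000501). With 1 library left out its adjusted p was at least 0.0887.

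Hepatocyte identity genes were higher as a list (camera adjusted p = 0.00328), and markers of macrophages (0.00470), endothelial cells (0.00470), stellate cells (0.0112) and lymphocytes (0.0444) were lower. With an estimated correlation the adjusted p was 0.803 for each of these 5 lists, and 0 of their members passed over all genes. Adjusted over the list alone, Cd4 of the lymphocytes (1 of 6 members) was lower, at 2.15 ± 0.62 and 0.733 ± 0.341 CPM, and 0 members of the other lists passed. These differences were larger in the shallow libraries. Median log2 differences from shNC were -1.33 for macrophages, -1.40 for stellate cells and -0.67 for endothelial cells in the shallow pair, against 0.07, 0.23 and 0.07 in shTbl1xr1 3 and 4. Hepatocyte identity had medians of 0.58 and -0.01 in the same pairs, and lymphocytes -1.25 and -0.35. In the deeper libraries only, 0 of these 5 lists passed (adjusted p = 0.859, 0.510, 0.859, 0.859 and 0.226 for hepatocyte identity, macrophages, endothelial cells, stellate cells and lymphocytes). There drug metabolism (9.1e-10), oxidative stress (9.9e-08), lipogenesis (8.3e-07), fatty acid oxidation (8.3e-07) and mitosis (8.3e-06) kept their direction and their call at the preset correlation. With an estimated one, over all libraries, 0 lists passed. The mean log2 level of mitosis relative to shNC was -0.13 in shTbl1xr1 3 and -0.65 in shTbl1xr1 4. Its call in the deeper libraries only thus rests largely on shTbl1xr1 4. With the shallow shTbl1xr1 pair only, lipogenesis, fatty acid oxidation and mitosis kept their direction and did not pass (adjusted p = 0.221, 0.708 and 0.301), nor did lymphocytes (0.465).

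When libraries were scaled by size alone, the macrophage, endothelial, stellate and lymphocyte lists did not pass (adjusted p = 0.0940, 0.0567, 0.150 and 0.150), nor did lymphocytes with upper quartile scaling (0.0622). The macrophage list was also lost without shTbl1xr1 1 (adjusted p = 0.057), and the hepatocyte, macrophage, endothelial and stellate lists without shTbl1xr1 2 (0.076, 0.076, 0.088 and 0.11). The stellate list was also lost without shNC 3 or shTbl1xr1 4 (0.21 and 0.096), and the lymphocyte list in 7 of the 8 fits that left out a library, all but that without shNC 3. Albumin itself, at 47727 ± 6979 and 46746 ± 9011 CPM, had a log2 fold change of -0.03 (SE 0.31). Among single markers the macrophage gene Cd5l had -0.69, the stellate cell gene Dcn -0.80, the endothelial gene Tek -0.46, and Hgd, an enzyme of tyrosine breakdown in hepatocytes, 0.72, with adjusted p between 0.33 and 0.44. Bile duct and red blood cell markers did not pass (camera adjusted p = 0.220 and 0.535), with Prom1 at 2.07 (SE 0.72) and Hbb-bs at -0.53 (SE 0.42). Bile duct markers were higher and passed in the deeper libraries only (0.0167) and without shNC 3 (0.0471), both at the preset correlation. With an estimated one, over all libraries, their adjusted p was 0.803. Their mean log2 level was 1.54 above shNC in shTbl1xr1 3 and between -0.11 and -0.05 in the other 3. Without shTbl1xr1 3 the list turned lower (0.817) and Prom1 had 0.74. Neutrophil markers were not tested as a list because 4 members passed the expression filter, and S100a8 had 0.81 (SE 0.58). In the deeper libraries only, a fit in which the list was tested, it was higher (camera adjusted p = 0.00325 at the preset correlation). Over the 4 members that passed with all libraries, the mean log2 level relative to shNC was -1.51, -0.55, 1.55 and 0.45 in shTbl1xr1 1 to 4. In shNC it was -0.55 to 0.66.

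**Figure D3:**
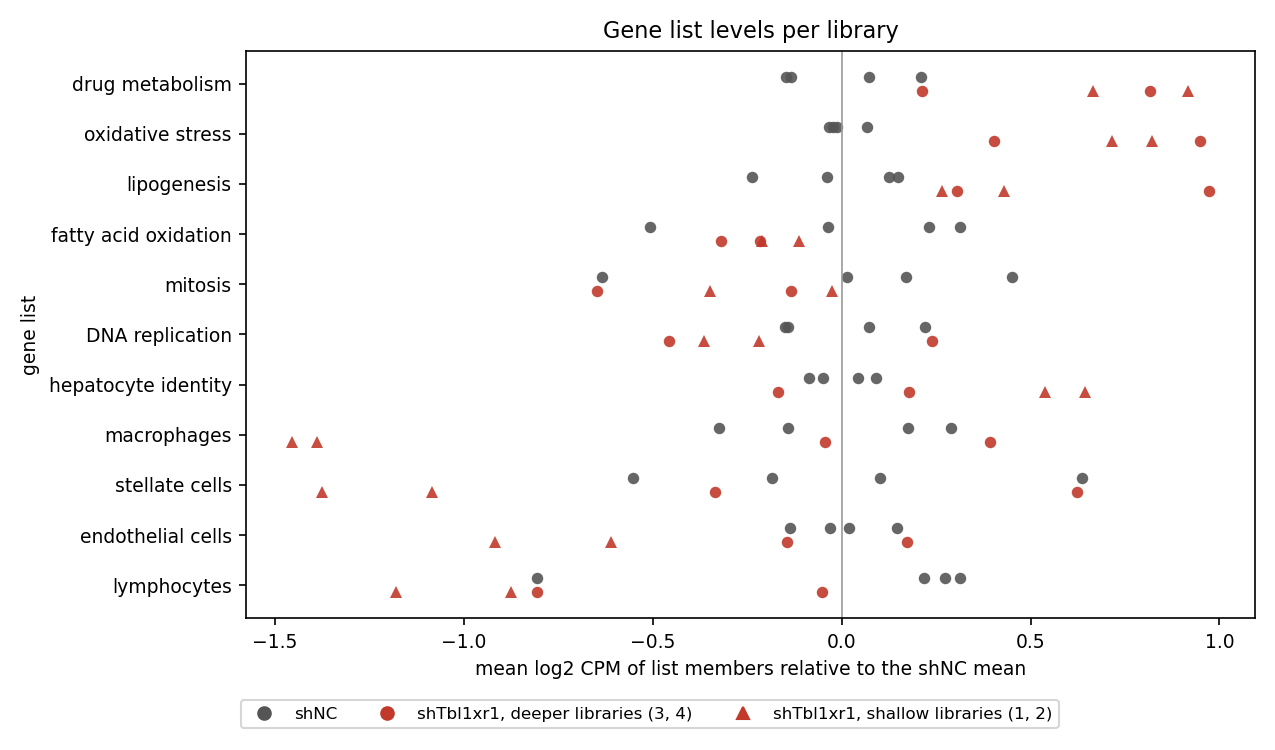
Each point is the mean log2 CPM of the tested members of a gene list in 1 library, relative to the shNC mean, with grey circles for shNC, red triangles for shTbl1xr1 1 and 2 and red circles for shTbl1xr1 3 and 4. All 4 shTbl1xr1 libraries lie above the shNC range for drug metabolism, oxidative stress and lipogenesis. For drug metabolism the margin is narrow, with 0.214 in shTbl1xr1 3 and 0.210 in shNC 4. The macrophage and stellate cell lists lie below the shNC range in shTbl1xr1 1 and 2.

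None of the remaining lists passed by camera with all 8 libraries, TMM scaling and no block. The adjusted p was 0.0855 for acute phase, where Orm2 alone passed over all genes and over the list alone, 0.196 for stress response, 0.220 for bile acid synthesis and transport, 0.220 for fetal liver genes, 0.284 for periportal, 0.356 for p53 targets and 0.362 for YAP and TGF beta targets. It was 0.849 for cholesterol synthesis, 0.984 for pericentral and Wnt, for circadian clock, for sex-biased liver genes and for interferon response, and 0.997 for immediate early. Several passed in other fits at the preset correlation, where with an estimated one and all libraries each had an adjusted p of 0.803 or more. Acute phase was higher without shNC 2, shNC 3, shTbl1xr1 3 or shTbl1xr1 4 (adjusted p = 0.0131, 0.0061, 0.0487 and 0.0096) and with the shallow shTbl1xr1 pair only (0.0085). Without shTbl1xr1 3, bile acid synthesis and transport was higher (0.0487) and stress response and YAP and TGF beta targets were lower (both 0.0166). Cholesterol synthesis was higher without shNC 2 (0.0225) and lower in the deeper libraries only (0.00232), where pericentral and Wnt (0.00140) and sex-biased liver genes (0.0396) were lower and periportal (0.0171) was higher. The mean log2 level of cholesterol synthesis relative to shNC was -0.53 in shTbl1xr1 3 and -0.05 in shTbl1xr1 4. In the same order, pericentral and Wnt had -0.51 and -0.10, periportal -0.07 and 0.56, and sex-biased liver genes -1.54 and -0.76. Except for the sex-biased genes, these calls in the deeper libraries thus rest largely on 1 library. Akr1d1, of bile acid synthesis, was 1 member of its list higher over the list alone (log2 fold change 0.77, SE 0.18), and Ccnd1 was 1 member of the pericentral and Wnt list lower, where Axin2 had -0.64 (SE 0.21) and Glul 0.22 (SE 0.32). In the clock list Dbp and Ciart (2.17, SE 0.61, and 1.68, SE 0.49) were higher and Clock (-0.54, SE 0.16) lower over the list alone. Sex-biased genes moved both ways, with Cyp2b9 lower and the male-biased Mup20 and Selenbp2 (1.58, SE 0.43, and 1.37, SE 0.45) higher over the list alone, a mean of -0.28, a median of 0.56 and a fry adjusted p of 0.00236 for change in either direction. The stress response list had a mean of 0.06 and a median of -0.13, with the chaperone gene Hsp90b1 at -0.74 (SE 0.19). The members with the smallest p in the remaining lists were Bbc3 (0.69), Tm7sf2 (0.86), Ass1 (0.55), Oasl1 (0.77), Socs2 (1.59), Axl (-0.56) and Peg3 (-1.03), with adjusted p between 0.29 and 0.55, and Cdkn1a had 0.12 (SE 0.32).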

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

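In this part, the test of the length trend as the whole cause, the narrowing of the knockdown test to proportional differences, the bile duct marker test and both clock tests were chosen after the results were seen. Of 128 groups of 4 values tested, 10 held a library far from the other 3, where chance gives about 1 in 20. In shTbl1xr1 4, Acacb at 61.9 CPM (others 23.9 to 28.3) and Cd4 at 1.24 CPM (others 0.515 to 0.626). In shTbl1xr1 3, Prom1 was at 9.28 CPM (others 0.967 to 1.83), Hbb-bs at 374 CPM (others 148 to 180), S100a8 at 4.57 CPM (others 0.83 to 1.46) and Fgf21 at 12.8 CPM (others 0.174 to 0.690). In shNC 3, Axl was at 44.9 CPM (others 31.16 to 32.97) and Alb took 4.37% of counts (others 5.54% to 5.73%). The total of shNC 2 was 27537235 counts (others 25811763 to 25890652), and the mitochondrial share of shNC 1 was 7.34% (others 4.96% to 5.15%).

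Libraries shTbl1xr1 1 and 2 stood apart from the other 6 on the first principal component. Lower sequencing depth, as total counts, is argued against as the cause, since 89.5% of that gap remained after every library was thinned to the shallowest total. The slope of the deeper pair's differences on theirs was -0.0013 (range over 6 splits of the controls -0.094 to 0.075). It argues against differences proportional to the knockdown, which is deeper in these libraries, as the whole cause. A handling or batch difference shared by the 2 libraries would also lower the slope, so a proportional part is not excluded. Long transcripts were low in the 2 libraries, with a Spearman correlation across genes of -0.58 between length and their difference from shTbl1xr1 3 and 4, against at most 0.39 in size in 45 contrasts of the other 6, so length-dependent loss of RNA may contribute, but 89.0% of the gap remained once each library's length trend was removed, which argues against it as the whole cause. Library shNC 1, without knockdown, deviated from its group mean in a similar direction. Its deviations had correlations across genes of 0.38 and 0.37 with those of shTbl1xr1 1 and 2, against -0.27 to -0.0018 for the other shNC libraries. Its score (-9.29) and mitochondrial share (7.34%) were also the nearest. Some variation of this kind thus occurs without knockdown, which does not decide the cause. A proportional response as part of the cause, a response to deeper knockdown that is not proportional, and a handling or batch difference stay open. Both libraries that stood apart are shTbl1xr1, and the labels give no batch.

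Markers of macrophages, stellate cells and endothelial cells were low in the same 2 libraries, with a median log2 difference from shNC of -1.09 over 50 markers. Length-dependent loss of RNA is argued against as the whole cause of that, because 10000 lists matched on length and expression had a median of -0.13. The markers' median lay at percentile 0.01 of these lists, the lowest possible. Genes of the matched lists were drawn independently, while markers move together, with estimated correlations of 0.64 for macrophages, 0.64 for stellate cells and 0.58 for endothelial cells. The percentile therefore overstates the certainty. Fewer non-hepatocyte cells of every kind was tested by bile duct markers, whose median of -0.09 over 9 genes lay 0.99 above the other markers (SE of the difference 0.33). That SE takes genes as independent, while genes of a list move together, so the test cannot decide. Below 0 in this pair were 5 of 9 bile duct, 5 of 6 lymphocyte, 4 of 4 neutrophil and 5 of 7 red blood cell markers. Fewer non-hepatocyte cells of every kind, and a lower share of macrophages, stellate and endothelial cells, or of their RNA, in these 2 pieces of liver stay open. They were not tested further.

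The clock list did not pass (camera adjusted p = 0.984), but its arms stood apart from shNC in 3 of 4 shTbl1xr1 libraries. The mean of 8 genes of the Dbp arm minus that of 5 genes of the Bmal1 arm was 1.32, 1.43, 0.03 and 3.20 on the log2 scale in shTbl1xr1 1 to 4, and -0.77 to 0.78 in shNC. Loss of corepressor at REV-ERB targets would raise the Bmal1 arm, and no rise was seen. That arm lay below the shNC mean in 4 of 4 shTbl1xr1 libraries. In shTbl1xr1 3 it was inside the shNC range (-0.09, against -0.29 to 0.53). Another hour of collection could lower the arm and hide a rise, so such a loss is not excluded. Other time of day at collection stays open, since the arms moved in opposite directions in 3 of the 4 libraries, which decides nothing, and the labels give no hour.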

How the results depend on the processing

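Fits of the deeper or the shallow libraries, thinning, library weights, length correction and list tests under upper quartile or library size scaling were chosen after seeing the data. Each of the 7 called genes kept its direction in every fit. Their groups did not overlap, so leaving out libraries could hardly have turned it. Calls depended on single libraries: over the fits that left out 1 library, genes higher ranged from 0 to 28, genes lower from 0 to 6, lists higher from 3 to 6 and lists lower from 2 to 6, and Tbl1xr1 from -2.71 to -1.79 (adjusted p 0.0758 to 0.694). The lists lower numbered 2 without shTbl1xr1 2 and 3 without shTbl1xr1 4. Depth limits low genes in shTbl1xr1 1 and 2, but thinning to equal totals, which leaves the mitochondrial shares unequal, left 5 genes higher and 1 lower, 5 of them shared (without Cyp2c55 and Pls1).

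Counts of genes higher and lower against 6 and 1 were 3 and 1 with library size alone, which moved the median of all genes to -0.27, 12 and 1 with no filter, 237 and 39 with DESeq2, 5 and 0 with limma-voom (893 and 540 at an unadjusted p under 0.05), and 38 and 4 with 1 surrogate variable. They were 7 and 0 with deeper libraries only (985 and 677 unadjusted), 3073 and 3021 with the shallow shTbl1xr1 pair only, 30 and 2 with limma-voom with sample weights (without Cyp2b9), and 26 and 3 with the length trend removed, where all 7 called genes passed. On simulated counts DESeq2 called 171 genes, 20.5% of them false, where edgeR called 98. That simulation held no shift shared by shTbl1xr1 1 and 2, so it cannot say how much of the difference here is false calls. The cause of these changes in the counts was not tested. Tbl1xr1 passed with DESeq2 (-2.13), 1 surrogate variable (-1.67) and the shallow shTbl1xr1 pair only (-3.88, adjusted p = 6.6e-05), and its adjusted p over all fits with all libraries or 1 pair left out reached 0.579. Lists higher and lower against 4 and 6 were 0 and 0 with an estimated correlation, 2 and 0 by fry, 4 and 2 with library size alone and 4 and 3 with the shallow shTbl1xr1 pair only.

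Some log2 fold changes changed sign, among them those of Tm7sf2 (0.86 with all libraries), S100a8 (0.81), Fgf21 (0.78) and Axl (-0.56). With library size alone the log2 fold change was -0.16 for Gps2, -0.22 for Pcna, -0.21 for Cdkn1a and -0.20 for Glul. With 1 surrogate variable it was -0.012 for Gps2, -0.012 for Tm7sf2, -0.0065 for Cdkn1a and -0.21 for Glul. With deeper libraries only it was -0.046 for Gps2, -0.21 for Tm7sf2, 0.019 for Axl, -0.042 for Pcna, -0.047 for Cdkn1a and -0.34 for Glul. With the shallow shTbl1xr1 pair only it was -0.46 for S100a8, 0.00086 for Alb and -2.04 for Fgf21, and with the length trend removed -0.066 for Gps2 and -0.017 for Pcna. Leaving out 1 library gave -0.057 to 0.37 for Cdkn1a, -0.13 to 0.082 for Alb, -0.0016 to 0.24 for Pcna, -0.074 to 0.44 for Glul, -0.068 to 1.11 for S100a8 and -2.69 to 2.05 for Fgf21. In the deeper libraries only, 9 lists changed direction, acute phase and YAP and TGF beta targets without passing in either fit. Of the other 7, cholesterol synthesis (adjusted p = 0.00232), pericentral and Wnt (0.00140) and sex-biased liver genes (0.0396) were lower, and hepatocyte identity (0.859), macrophages (0.510), stellate cells (0.859) and endothelial cells (0.859) no longer passed. The cause of these changes of sign was not tested.

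The replicate numbers were not taken to pair the libraries, since same-numbered deviations had correlations of 0.38, -0.074, 0.30 and 0.12 for numbers 1 to 4, not each above 0.1, with 2 of 4 shTbl1xr1 libraries closest to their own number. With the replicate block 4 genes were higher and 1 lower, 4 of them shared (without Orm2, Cyp2c55 and Cd276, and with Cib3, named after its values were seen), and Fgf21 had -0.22. At the preset correlation DNA replication (lower) and acute phase (higher) passed with the block (camera adjusted p = 0.0393 for both) while lymphocytes no longer did (0.1003). With an estimated one, over all libraries and without the block, both had an adjusted p of 0.803. Over all results, among those that answer the comparison 75 values were the same, 37 moved and 3 newly passed, and among single genes and lists 1725 were the same, 91 newly passed, 106 no longer passed and 36 changed sign. For lists that count holds the 7 that passed in either fit, and 49 more changes of direction, over all lists and alternatives, passed in neither.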

Other observations

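Gene families were looked at after the data were seen, and the fixed lists held 5 Gst, 8 Cyp2, 3 Cyp4, 2 Ugt, 2 Ces, 1 Mup, 1 Sult and 0 Abcg genes of those tested. All 20 tested glutathione S-transferase (Gst) genes had positive log2 fold changes in shTbl1xr1, with a median of 0.95. In 10 of the 20 every shTbl1xr1 library lay above every shNC library. Of all tested genes 3.88% did so, where the average over all arrangements of the libraries is 1.43%. Of these 20 genes 1, Gstm3, which the fixed lists held, passed the edgeR threshold over all genes. The family's mean log2 level was 1.08 higher and lay above the shNC range in 4 of 4 shTbl1xr1 libraries (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.229 over 8 families). An adjusted p under 0.05 would need most of the 8 families at that smallest p. The signs were positive for 18 of the 20 when libraries were scaled by size alone or the length trend was removed, and for 15 of 20 in the deeper libraries only.

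Major urinary protein (Mup) genes, secreted liver products with male-biased expression, showed a median log2 fold change of 2.28, and all 20 tested were positive. In 6 of them every shTbl1xr1 library lay above every shNC library, and 0 passed the edgeR threshold over all genes, with 17 at an unadjusted p under 0.05 and higher. The family's mean level was above the shNC range in 3 of 4 shTbl1xr1 libraries (exact permutation p = 0.0571, adjusted p = 0.229), and 19 of 20 were positive with size scaling and 18 of 20 in the deeper libraries only. Near-identical Mup genes share reads, so these counts are not independent. Among 32 genes of the Cyp2 family 28 were positive, 3 passed the threshold (Cyp2a5 and Cyp2c55 higher, Cyp2b9 lower), and the mean level was 0.48 higher (exact permutation p = 0.171). With size scaling 21 of the 32 were positive, and 21 of 34 in the deeper libraries only. The Ugt, Cyp4, Ces, Sult and Abcg families had 16 of 17, 11 of 14, 10 of 14, 7 of 8 and 3 of 5 genes positive, with exact permutation p of 0.114, 0.229, 0.543, 0.143 and 0.343. With size scaling 11, 8, 7, 5 and 2 of them were positive, and in the deeper libraries only 11 of 17, 7 of 14, 6 of 14, 4 of 9 and 4 of 5.

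In the deeper libraries only, 4 shNC against 2 shTbl1xr1, 7 genes passed, of which 4 also passed with all libraries. The other 3, named after their values were seen, were Mmp15, a membrane-bound matrix metalloproteinase (log2 fold change 1.71, SE 0.18, adjusted p = 0.0305 by edgeR), Slc5a6, a vitamin transporter (1.53, SE 0.16), and the predicted gene Gm3839 (1.74, SE 0.18).

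The 35 ways to part the 8 libraries into 4 and 4 were tested to see whether chance parting of the libraries could give as many calls. For genes, the real split called 7 and the highest of the other splits called 0. Thus 1 of 35 splits gave as many, the smallest share this test can give. Chance is argued against for that count but not excluded. For gene lists, the real split called 10 and the highest other split 19, and 19 of 35 splits gave as many, so chance cannot be excluded for the number of lists. Of the other splits that called 10 or more lists, 6 kept shTbl1xr1 1 and 2 together and 12 parted them, including the one with 19.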
